A study of Mus musculus with 4 samples.

How the data were processed

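Cells of 2 kidneys from a single C57Bl/6 mouse were dissociated with 0.2 mg/mL Liberase TM for 45 min at 37 °C and 800 rpm, passed through 100 and 40 µm filters, sorted by flow cytometry and loaded into 2 wells of a 10x Chromium run, 40000 cells per well, per the labels' protocols. Each well gave a 3' gene expression library and a library of cholesterol-modified oligos (CMOs), DNA tags that anchor in the plasma membrane and mark the pool a cell came from (MULTI-seq). The pooling table lists 24 CMOs in 8 groups of 3. The labels do not say how the cell pools behind the 8 groups differed, so the groups are named here by the number of their column, 0 to 7.

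The expression values were raw counts of unique molecular identifiers (UMIs) per cell and gene, as deposited by the authors, who list kallisto, bustools and the mm10 build in the submitters' processing notes without versions. The CMO values were the natural log of 1 plus the count, summed by the authors over the 3 CMOs of a group, and were turned back into counts by the inverse of that log and rounding. For well 2 the authors deposited a table per cell with a cell type name, a CMO call, a computational doublet call and the score behind it, a fraction from 0 to 1. No such table was used for well 1. The limits the authors set on cells and genes are not given in the sources used here. The smallest cell held 501 UMIs in each well. The highest mitochondrial share of a cell was 59.99% in either well, so a limit near it may have been set before deposit. Of 19222 gene identifiers in either well's gene table, 19211 matched the reference names, and the 18665 genes listed for both wells, with 99.99% of UMIs, were used. Droplets with at least 200 detected genes were kept, 23978 in well 1 and 21120 in well 2, with no further limit on the mitochondrial share.

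CMO calls were made per well and group with a Gaussian mixture of 2 components on the log counts, a group being positive at a posterior of 0.5. A droplet with 1 positive group was called a CMO singlet, with 2 or more a CMO doublet and with 0 a negative. A droplet with several cells of the same group is called a singlet by this rule, and a droplet with 1 cell and CMOs of another group can be called a doublet, so the doublet share is no bound on the share of droplets with more than 1 cell. On 5000 simulated droplets the mixture recovered 97.7% of doublets and called 2.09% of singlets doublets, while a rule based on the 0.99 quantile of a negative binomial background, kept as an alternative, recovered 99.8% and called 18.0%. The simulation drew the CMO counts of all cells from the same distribution, with 1 or 2 cells per droplet. On the data the background rule gave lower doublet shares than the mixture, 40.5% and 39.1% against 41.8% and 40.4% in the wells. The simulated rates are therefore not error rates for these data. In well 2 the mixture called 87.3% of the authors' doublets a doublet and 79.0% of their singlets a singlet, and left 14.9% of their singlets negative. Of 10442 droplets that both called a singlet, 10441 had the same group.

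Singlets of both wells were clustered (counts scaled to 10000 per cell, 2000 variable genes, 30 principal components, 15 nearest neighbours, Leiden resolution 1.0; python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, anndata 0.12.19, matplotlib 3.10.9). Of 43 clusters, 35 received an "X-like" name from 18 marker lists fixed before the data were examined. The limits for a name were set after the clusters had been seen: a mean log2 marker level of 2.5 above the median cluster, 3 markers at 4-fold, a lead of 0.5 over the next class and a marker UMI in 50% of cells. The 15 named classes held 21435 of 23906 singlets. Some named clusters also scored high for a second class. A principal-like cluster of 386 cells scored 4.57, and 3.70 for distal convoluted tubule, so the principal-like class may be mixed. The others were small. A thick ascending limb-like cluster of 33 cells scored 4.98, and 3.97 for endothelial. A macrophage-like cluster of 70 cells scored 4.76, and 4.18 for thick ascending limb, and another of 49 cells 4.47, and 3.62 for endothelial. They were kept, so the singlets may include droplets with several cells of the same group. The 8 unnamed clusters held 10.4% of singlets, 10.1% of doublets and 3.17% of negatives. Doublets, negatives and simulated pairs took the class most frequent among their nearest singlets. The authors' cell type names were not used for classes, because they cover well 2 alone and 3 of 15 differ from the marker content of their cells. Simulated pairs were sums of 2 random singlets of different CMO groups of a well, as many as its doublets.

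Doublet scores were computed per well without the CMO data: Scrublet in scanpy (30 principal components, 2.0 simulated doublets per cell), a neural network with hidden layers of 64 and 32 units trained to separate observed from simulated droplets (5 folds, each scored by a network that had not seen it), total UMIs and detected genes. Each was compared with the CMO calls by the area under the receiver operating characteristic curve (AUROC) and by average precision. Positivity for markers of 2 classes meant at least 3 UMIs from the markers of each. It was also computed after thinning each droplet to 1000 UMIs. Intervals of single shares are exact binomial intervals (Clopper-Pearson, 95%) and cover counting error alone.

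Raw counts were summed per well over singlets, over doublets and over the singlets of each CMO group. Sums of doublets and singlets (4 sums) were compared with edgeR 4.0.16 (R 4.3.3, limma 3.58.1; filterByExpr, TMM, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05), and the 16 sums of CMO groups with an F test over all groups. Standard errors were the log2 fold change over the root of the F statistic. Both wells took cells of the same suspension from a single mouse, so p-values measure the technical spread between wells, and cells were never used as replicates. A sum of randomly paired singlets has the profile of the singlet sum, so the first test measures how CMO doublets depart from random pairs of CMO singlets. CMO calling differed between classes, with 33.1% of NK cell-like and 0.0123% of macrophage-like droplets negative for all groups. A departure was not told apart from such differences in calling or from the limits on cells. It does not show that cells paired unequally.

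The sums are paired by well, since the labels give each well as a run of its own. Over 6852 genes with a mean of at least 20 CPM (counts scaled to library size), the deviations of the singlet and the doublet sum of a well from their class means correlated at 0.0862. The test without the pairing had been fixed before the data were examined, and the test with the well as a block is given beside the calls, counts of genes and list counts that it changes at the chosen settings, and beside the counts of genes of the doublet test under the alternatives. It was not run on leaving out a sum or for the group test under the alternatives, and calls of single genes under the alternatives are given without it. On simulated counts with 200 changed genes, the doublet test recovered 84% of genes changed 1.25-fold and 100% of those changed 1.5-fold, 2-fold or 4-fold, with 5 false calls among 18572 genes. The group test recovered 8%, 70%, 100% and 100%, with 5 false calls among 15445 genes. In the simulation of the doublet test all genes had the same common dispersion, without the differences in spread between genes of the real sums. Its recovery therefore does not hold for genes with a larger spread, and a gene that did not pass is not shown to be unchanged. In the data Slc26a4 was 1.49-fold higher in doublets and did not pass in edgeR without the block (adjusted p = 0.338), but did with it (2.94e-04).

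Named genes followed a rule fixed before the data were examined: among genes that passed the test with a mean CPM of at least 20, the 10 largest rises and the 10 largest falls with the same sign in both wells, or for the group test the 20 with the largest range of group means. In addition, 26 fixed lists were counted, with up to 4 of their most abundant members named: 18 cell type marker lists (proximal tubule, thick ascending limb, thin limb, distal convoluted tubule, principal cell, intercalated cell, podocyte, endothelial, stromal and smooth muscle, macrophage, dendritic cell, neutrophil, T cell, NK cell, B cell, urothelium, erythroid, cycling) and 8 others (early response and dissociation genes, mitochondrial genes, cytoplasmic ribosomal proteins, tubule injury, proximal transporters, gluconeogenesis, distal sodium and water transport, haemoglobins). The lists overlap in part: the haemoglobins are also erythroid markers, the distal transport list shares Slc12a1, Slc12a3, Aqp2, Aqp3, Scnn1b and Scnn1g with tubule markers, and the proximal tubule markers share Slc34a1, Lrp2, Slc5a2, Slc5a12 and Slc22a6 with the proximal transporters. A further overlap is not reported here. The tissue itself expresses the tubule, vascular and stromal lists. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. UMIs of Hba-a1 and Hba-a2, and of Hbb-bs and Hbb-bt, come from near-identical copies and may have been split between the genes of each pair, so their single values are uncertain.

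Alternatives were fixed beforehand: other CMO calls (posterior 0.9, the background rule, the authors' calls in well 2), at least 500 genes, a mitochondrial share of at most 30%, DESeq2 1.42.0, other scaling, no filter on genes, the block, thinning, leaving out sums, other Leiden resolutions, classes by marker score and other score settings. Those chosen after the data had been seen were leaving out an unnamed cluster of high haemoglobin and mitochondrial content in either test of genes, leaving out cells with a haemoglobin UMI, and restricting the AUROC to doublets with rare pairs of classes. That cluster held 1280 singlets with a median of 659 UMIs and a median mitochondrial share of 48.4%. It is called haemoglobin-rich for its summed counts alone. Only 13.9% of its cells held an erythroid marker UMI, so it is not a class of red blood cells. The sums held between 5421281 and 60746701 UMIs.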

Results

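Expression and CMO counts were measured in droplets from mouse kidney in 2 wells, each with 1 expression library and 1 CMO library. Well 1 held 24057 cells with 124884887 expression UMIs, a median of 3752 UMIs and 1628 genes per cell, and 25614324 CMO counts. Well 2 held 21179 cells with 116222078 expression UMIs, a median of 3929 UMIs and 1687 genes per cell, and 23562536 CMO counts. The middle of the cells, from the lower to the upper quartile, lay between 1846 and 6791 UMIs in well 1 and between 1858 and 7099 in well 2. The stated purpose of the series was to learn how well doublets, droplets with more than 1 cell, can be found by computation. The comparisons therefore set CMO doublets against CMO singlets, computed scores against CMO calls, and the CMO groups against each other. Errors after ± are SDs over the wells (n = 2).

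CMO doublets made up 41.8% of labelled cells in well 1 (9048 doublets and 12594 singlets; exact 95% interval 41.1% to 42.5%) and 40.4% in well 2 (7683 and 11312; 39.7% to 41.1%), a mean of 41.1% ± 0.962. Another 9.74% and 10.1% of cells were negative for all groups. Among the doublets, 6589 and 5716 carried 2 groups, 1906 and 1510 carried 3, and 553 and 457 carried 4 or more. The highest group had a median of 450 counts in singlets of well 1 and 474 in those of well 2, against 15 for the second group, here over all cells before the limit on genes. In doublets the highest group had 773 and 820 counts and the second 141 and 140.

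Doublets held more RNA than singlets but less than pairs of singlets did. The median was 3383.5 UMIs in singlets and 5200.5 in doublets of well 1, and 3537.5 and 5502 in well 2, a ratio of 1.55 ± 0.013. Simulated pairs of singlets had medians of 7618 and 7994 UMIs, a ratio of 2.26 ± 0.0059. The ratio grew with the number of positive groups: it was 1.39 and 1.45 in the wells for 2 groups, 1.83 and 1.85 for 3 groups, and 2.45 and 2.40 for 4 or more. Negatives had medians of 1748.5 and 1762 UMIs.

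**Figure D1:**
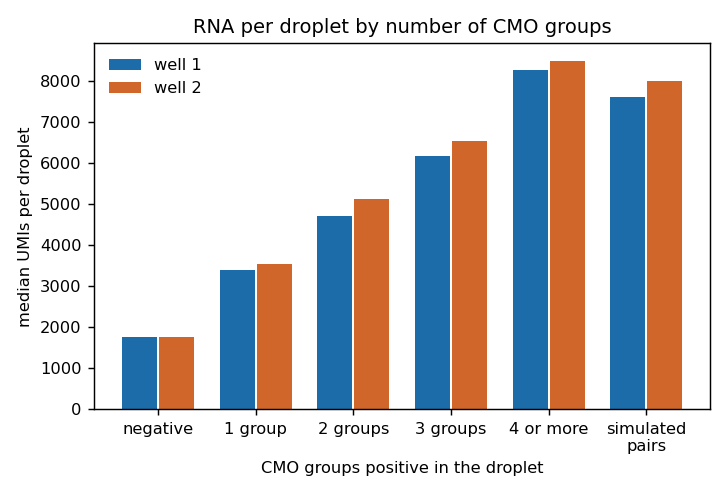
Median UMIs per droplet (vertical axis) by the number of positive CMO groups and for simulated pairs of singlets, with bars for each well. Droplets with 2 groups had medians of 4708 and 5121.5 UMIs, below the 7618 and 7994 of simulated pairs.

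Among the genes that rose in doublets were the chemokine Ccl8, haemoglobins and genes of contractile cells. Hbb-bs, a beta chain of the red blood cell's oxygen carrier, rose from 366 ± 30.5 to 992 ± 59.95 CPM (log2 fold change 1.44, SE 0.059, adjusted p = 2.81e-06, higher in both wells). Hba-a2 rose by 1.34 (adjusted p = 2.81e-06), Hba-a1 by 1.29 (2.81e-06) and Hbb-bt by 1.29 (0.00227). Their UMIs may be split between near-identical copies. Of the doublets' UMIs, 10 droplets held 54.8% for Hbb-bt, 39.9% for Hba-a2, 39.8% for Hba-a1 and 38.9% for Hbb-bs. At 500 genes per cell none of these 4 calls held, with log2 changes of 2.48 for Hbb-bs (adjusted p = 0.0539), 2.34 for Hba-a2 (0.0704), 2.24 for Hba-a1 (0.0870) and 2.76 for Hbb-bt (0.0575), and likewise without the haemoglobin-rich cluster (0.0543 to 0.0894). Hbb-bt did not pass at a posterior of 0.9 (0.81, adjusted p = 0.246) or by the background rule (1.09, 0.0539), and Hbb-bs stood at 0.93 at that posterior (0.0328). Over all alternatives the adjusted p of Hbb-bt reached 0.246. Ccl8, a chemokine of resident macrophages, had the largest change and rose from 17.0 ± 7.03 to 56.4 ± 7.04 CPM (log2 1.74, SE 0.195, adjusted p = 0.00227), but 10 droplets held 50.3% of the doublets' Ccl8 UMIs. Among cells without a haemoglobin UMI, Ccl8 stood at log2 1.37 (SE 0.278, adjusted p = 0.0627), and with the authors' calls in well 2 at 1.58 (0.0577). Its adjusted p ranged from 1.19e-15 to 0.0627 over the alternatives. Of the smooth muscle genes, Myh11, a myosin heavy chain, rose from 43.6 ± 2.75 to 83.4 ± 4.01 CPM (log2 0.94, SE 0.058, adjusted p = 4.71e-05), and Acta2, smooth muscle actin, from 273 ± 45.9 to 471 ± 5.95 CPM (log2 0.79, SE 0.085, adjusted p = 0.00177). With the authors' calls in well 2 Acta2 did not pass (0.96, adjusted p = 0.0701; 5.72e-10 to 0.0701 over the alternatives). Tpm2, a tropomyosin, rose by 0.79 (adjusted p = 6.06e-04), Rgs5, a pericyte signalling regulator, by 0.78 (1.91e-04) and Tagln, an actin-binding protein, by 0.77 (0.00123).

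The named genes that fell included markers of T and NK cells and of the thick ascending limb. Trbc2, part of the T cell receptor, changed by −0.40 (SE 0.057, adjusted p = 0.00958), Nkg7, a granule protein of killer cells, by −0.35 (SE 0.052, adjusted p = 0.0117), and Ltb, lymphotoxin beta, by −0.33 (adjusted p = 0.0167). Umod, the urinary protein of the thick ascending limb, went from 2404 ± 88.2 to 1903 ± 164 CPM (log2 −0.34, SE 0.053, adjusted p = 0.0145). Wfdc15b changed by −0.35 (SE 0.036, adjusted p = 0.00155), and Ppp1r1a, a phosphatase inhibitor, by −0.32 (0.00984). Ppp1r1b changed by −0.38 (adjusted p = 0.0264), Gpx6 by −0.37 (0.00441), Nccrp1 by −0.34 (0.0189) and Dnase1l3, a secreted nuclease, by −0.31 (0.0310). Dnase1l3 was no longer past the threshold without singlet replicate 1 or without doublet replicate 2, Ltb without doublet replicate 1, and Ppp1r1b without doublet replicate 2. With the authors' calls in well 2 none of these 10 falls passed in edgeR, with Trbc2 at −0.24 (adjusted p = 0.743), Nkg7 at −0.05 (0.958) and Umod at −0.15 (0.599), the highest values over their alternatives. At a posterior of 0.9 Umod (adjusted p = 0.0614), Ltb, Ppp1r1b, Nccrp1 and Dnase1l3 did not pass. After thinning Nkg7 (adjusted p = 0.142), Gpx6, Ppp1r1b, Nccrp1 and Dnase1l3 did not. Umod, Ppp1r1b and Nccrp1 also failed at a mitochondrial share of at most 30%. Umod (adjusted p = 0.137), Nkg7, Ltb, Ppp1r1b and Nccrp1 failed among cells without a haemoglobin UMI, Ppp1r1b at 500 genes and Dnase1l3 without the haemoglobin-rich cluster. Among cells without a haemoglobin UMI the log2 changes stayed negative, at −0.30 for Umod, −0.27 for Nkg7, −0.30 for Ltb, −0.32 for Ppp1r1b and −0.32 for Nccrp1. In all, 214 of 18626 genes passed, 180 higher and 34 lower, and 2289 had an unadjusted p under 0.05. Without singlet replicate 2, 447 genes passed. With the well as a block 1684 genes passed, 888 higher and 796 lower, among them all 214. With the authors' calls in well 2, 64 passed, 62 higher and 2 lower, and 0 in edgeR with the block as well (1501 at an unadjusted p under 0.05). DESeq2 called 199 genes, 173 of them shared.

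**Figure D2:**
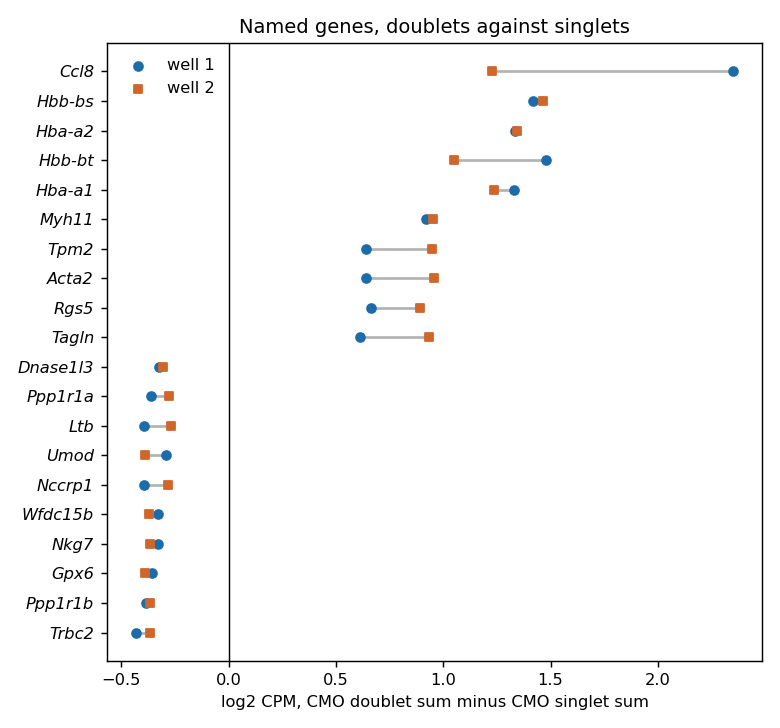
Difference in log2 CPM, doublet sum minus singlet sum, on the horizontal axis for 20 named genes, with a point per well. The haemoglobin genes and Ccl8 lie farthest to the right, and the wells differ most for Ccl8.

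All 13 mitochondrial genes rose, with mt-Cytb at log2 0.40 (adjusted p = 0.00230) and mt-Nd1 at 0.44 (4.71e-05). Each of the lists named next is given with its counts over all genes, then those adjusted over the list alone. All 4 haemoglobins and all 5 erythroid genes rose in either count, with Alas2, an enzyme of haem synthesis, at 1.32 (adjusted p = 0.0111). Of 10 stromal and smooth muscle genes 5 rose in either count, the fifth being Pdgfrb (0.53, adjusted p = 0.0194), while Dcn, of fibroblasts, did not pass (−0.07, 0.791). All 5 thick ascending limb genes fell in either count, among them Slc12a1, the salt transporter of that segment (−0.27, adjusted p = 0.00435), Egf (−0.27, 0.0212), Ptger3 (−0.29, 0.0171) and Cldn16 (−0.49, 0.0237). Of 7 intercalated cell genes 1 rose, the transcription factor Foxi1 (0.53, adjusted p = 0.0493), and 7 adjusted over the list alone. Atp6v1g3, a proton pump subunit, did not pass over all genes (0.39, 0.263), but did with the well as a block (7.89e-07). One T cell gene of 7 fell, Trbc2, and 5 adjusted over the list alone; 1 NK cell gene of 6 fell, Nkg7, in either count; 1 dendritic cell gene of 6 fell, Ccr7 (−0.28, 0.0310), and 2 adjusted over the list alone. Of 16 early response genes 1 rose, Nr4a1 (0.24, adjusted p = 0.0222), and 3 rose and 1 fell adjusted over the list alone. Of 11 distal sodium and water transport genes 1 fell, Slc12a1, and 3 rose and 2 fell adjusted over the list alone. Alas2, Pdgfrb, Cldn16, Foxi1 and Nr4a1 were named after their values had been seen, Pdgfrb, Foxi1 and Nr4a1 because they complete a count of 5 or fewer.

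For the other 15 lists edgeR called 0 genes over all genes. Among their 181 members 61 had an unadjusted p under 0.05, and DESeq2 called 3. Adjusted over the list alone, 3 of 7 principal cell genes, 1 of 5 thin limb genes and 1 of 7 tubule injury genes were higher, and 3 of 7 macrophage genes, 1 of 12 proximal tubule genes and 1 of 8 endothelial genes were lower. That adjustment called 0 of 5 distal convoluted tubule, 7 podocyte, 5 neutrophil, 6 B cell, 3 urothelium, 6 cycling, 85 ribosomal, 13 proximal transporter and 5 gluconeogenesis genes. Fxyd4, a sodium pump regulator of principal cells, stood at log2 0.22 (adjusted p = 0.0652), Aqp2, the water channel, at 0.08 (0.570), C1qb, a complement gene of macrophages, at −0.14 (0.173), Kap, a proximal tubule transcript, at −0.14 (0.304), and Emcn, an endothelial surface protein, at −0.14 (0.156). With the well as a block all of these passed, with adjusted p = 6.85e-07 for Fxyd4, 0.0185 for Aqp2, 2.26e-04 for C1qb, 2.25e-05 for Kap and 2.26e-04 for Emcn. With the well as a block, the lists changed as follows. Lower genes numbered 55 of the ribosomal proteins, 5 of proximal tubule, 5 of T cell, 3 of macrophage, 3 of NK cell, 3 of proximal transporters, 3 of gluconeogenesis, 2 of endothelial, 2 of dendritic cell, 2 of early response, 2 of distal transport and 1 of distal convoluted tubule genes. Higher genes under that block numbered 7 of intercalated cell, 5 of principal cell, 5 of early response, 5 of distal transport, 2 of thin limb, and 1 each of podocyte, macrophage, neutrophil and tubule injury genes.

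Camera at the preset correlation placed the haemoglobins (adjusted p = 2.54e-115), erythroid (7.54e-111), mitochondrial (5.05e-65), stromal and smooth muscle (1.43e-23), intercalated cell (3.55e-10), principal cell (0.00880) and thin limb (0.0417) lists higher. It placed thick ascending limb (2.91e-14), ribosomal (1.00e-11), T cell (1.38e-09), NK cell (7.88e-05), dendritic cell (3.62e-04), proximal tubule (7.19e-04), proximal transporter (0.0209) and gluconeogenesis (0.0380) lists lower. With an estimated correlation none of these calls held: adjusted p = 0.0746 with an estimated correlation for the haemoglobins, the erythroid and the mitochondrial list, 0.0799 for stromal and smooth muscle and for thick ascending limb, 0.191 for intercalated, T, NK and dendritic cell, 0.519 for principal cell, thin limb and ribosomal, 0.522 for proximal tubule and gluconeogenesis, and 0.581 for proximal transporters. Fry called the mitochondrial list alone (adjusted p = 0.0243). The remaining camera values were 0.0605 for macrophage, 0.0990 for distal convoluted tubule, 0.212 for tubule injury, 0.244 for endothelial, 0.269 for neutrophil, B cell and early response, 0.511 for urothelium, 0.683 for cycling, and 0.7997 for podocyte and distal transport genes. The podocyte list had a median of 0.02 and a mean of −0.05, and camera gave it the direction down.

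Stromal and smooth muscle-like cells had the highest ratio of doublet to singlet share, at 2.46% ± 0.121 of singlets and 4.38% ± 0.286 of doublets (log2 0.83 ± 0.17; 0.65 in simulated pairs). Intercalated-like cells made up 1.45% of singlets and 2.34% of doublets (log2 0.69 ± 0.02; 0.63 in pairs), principal-like cells 7.54% and 9.82% (0.38 ± 0.03; 0.48), and neutrophil-like cells 0.701% and 0.899% (0.36 ± 0.06; 0.83). Thick ascending limb-like cells had the lowest ratio, at 10.0% and 7.14% (log2 −0.49 ± 0.06; −0.56 in pairs). These 5 of 14 classes were past 0.3 in both wells, 4 higher and 1 lower than in singlets, but the mean of simulated pairs was past 0.3 the same way in each of them. With the authors' calls in well 2 principal-like cells were no longer past 0.3 (0.249, with −0.003 in well 2), and neutrophil-like cells were not at 500 genes (0.248), at a mitochondrial share of at most 30% (0.221) or by highest marker score (−0.082). Random pairs gave ratios of like or larger size under the same assignment of classes, except for a smaller one in stromal and smooth muscle-like cells. Relative to simulated pairs, neutrophil-like doublets were lower (−0.47), stromal and smooth muscle-like doublets higher (0.18), and NK cell-like (−0.67) and T cell-like doublets (−0.60) departed most. The others were endothelial-like (−0.11; −0.35 in pairs), macrophage-like (0.13; 0.33), proximal tubule-like (−0.25; −0.23), dendritic-like (−0.26; −0.09), thin limb-like (0.27; 0.53), distal convoluted tubule-like (−0.20; −0.28), B cell-like (0.14; 0.20), T cell-like (0.00; 0.60) and NK cell-like cells (0.04 ± 0.43; 0.71). NK cell-like cells went opposite ways in the wells (−0.27 and 0.34). No test was made on cells. Podocyte-like cells (34 singlets) were too few to compare.

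**Figure D3:**
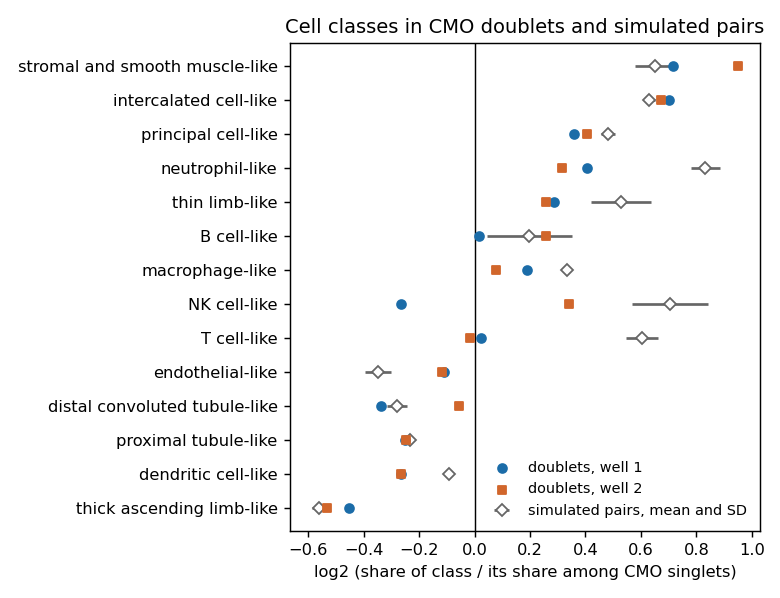
Log2 ratio of each class's share in doublets over singlets on the horizontal axis, by class, with a point per well and the mean and SD of simulated pairs. Stromal and smooth muscle-like and intercalated-like cells lie farthest to the right, thick ascending limb-like cells farthest to the left.

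Markers of 2 cell types occurred together more often in doublets. At least 3 UMIs of each of 2 classes were found in 89.5% ± 0.043 of doublets, 79.3% ± 0.573 of singlets and 98.7% of simulated pairs. With each droplet thinned to 1000 UMIs these were 47.3% ± 1.00, 32.9% ± 1.71 and 65.0% ± 1.90, over 8354 of 9048 and 7116 of 7683 doublets and 10713 of 12594 and 9696 of 11312 singlets with that depth. In thinned droplets, endothelial with macrophage markers were found in 2.25% ± 0.147 of doublets, 0.255% ± 0.018 of singlets and 5.31% ± 0.021 of pairs. Principal cell with macrophage markers were found in 1.14%, 0.0879% and 2.31%. Over 7 such class pairs, called rare, the shares were 6.22% ± 0.202, 1.05% ± 0.023 and 14.02%. They were chosen from these data as pairs in at most 0.3% of thinned singlets and at least 1% of simulated pairs. The low share in singlets and the high share in simulated pairs therefore follow from the choice, which did not use the doublets. Proximal tubule with endothelial markers reached 6.33% ± 0.767 of singlets and 8.50% ± 0.281 of doublets.

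The Scrublet score ranked doublets over singlets with an AUROC of 0.664 in well 1 and 0.669 in well 2 (mean 0.666 ± 0.0035). The neural network reached 0.713 and 0.712, total UMIs 0.634 and 0.637, and detected genes 0.624 and 0.628. Average precision was 0.605 and 0.599 for Scrublet and 0.660 and 0.646 for the network. In well 2 the authors' own score reached 0.764, with an average precision of 0.690. The authors' computational call marked 48.0% of CMO doublets of well 2 (3689 of 7683; exact 95% interval 46.9% to 49.1%), 11.9% of singlets (1342 of 11312; 11.3% to 12.5%) and 5.04% of negatives (107 of 2125; 4.14% to 6.05%). For doublets positive for a rare class pair the AUROC was 0.945 and 0.953 for Scrublet and 0.939 and 0.938 for the network. These were chosen by their own transcripts, in a test added after the data had been seen.

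**Figure D4:**
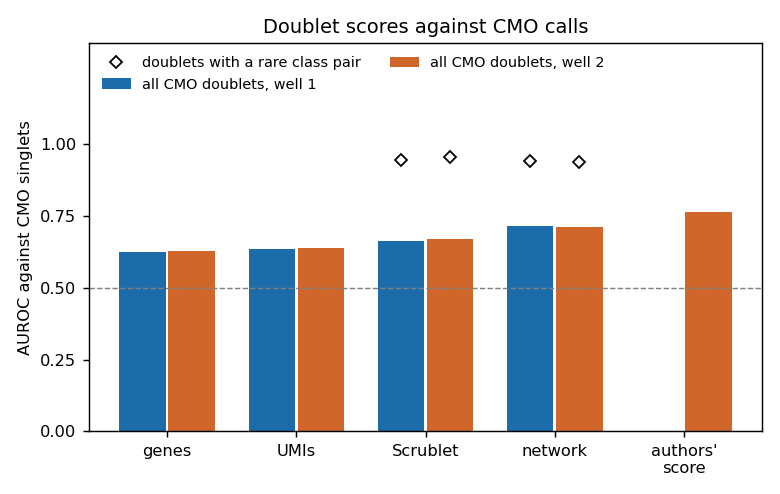
AUROC (vertical axis) of each score for CMO doublets against CMO singlets, per well, for all doublets and for doublets positive for rare class pairs. Scrublet reached 0.664 and 0.669 for all doublets, and 0.945 and 0.953 for rare-pair doublets.

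Genes of collecting duct principal cells differed between the 8 CMO groups, highest in group 1 and lowest in group 6. Hsd11b2, an enzyme that inactivates glucocorticoids, had a range of group means of 1.006 on the log2 scale (SD within groups 0.10, adjusted p = 0.00585). Aqp3 had 0.90 (0.0108), Aqp2 0.80 (0.0428), Scnn1g and Scnn1b, subunits of the sodium channel, 1.06 (0.00794) and 1.06 (0.0479), and Rhcg, an ammonia transporter, 0.92 (0.0217). Kcne1 had 1.20 (0.0241), Kcnq1 1.014 (0.0195), Tmem52b 0.97 (0.0245), Pappa 1.09 (0.0414), Ptges 0.84 (0.0460), Aif1l 0.82 (0.0447), Cldn7 0.75 (0.0256), Rnf186 0.74 (0.0451), Cav2 0.71 (0.0414), Scd2 0.71 (0.0242) and Arhgap24 0.68 (0.0414). Dlgap5 was highest in group 1 and lowest in group 7 (1.07, 0.0479), and Slc39a2, a zinc transporter, highest in group 6 and lowest in group 2 (0.94, 0.0242). Igha, an antibody heavy chain, had the widest range among genes that passed with a mean CPM of at least 20, at 5.92 (0.000747). However, a single droplet per well held 411 of its 453 UMIs and 3371 of its 3385 UMIs in group 4. Cd74 (0.50, 0.0414) and H2-Aa (0.54, 0.0414), of antigen presentation, were highest in group 6 and lowest in group 1, and were named after their values had been seen. Principal-like cells made up 10.7% ± 0.781 of the singlets of group 1 and 5.54% ± 0.353 of group 6, and macrophage-like cells ranged from 16.6% in group 1 to 21.4% in group 4.

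In all, 37 of 15490 genes differed between CMO groups, and 1216 had an unadjusted p under 0.05. With the well as a block 71 passed, among them all 37, and DESeq2 called 170 of 6000. Principal cell genes accounted for 5 of 6 tested (6 adjusted over the list alone), distal sodium and water transport genes for 5 of 11 (9) and distal convoluted tubule genes for 1 of 5 (4), the last being Tmem52b. In the other 23 lists edgeR called 0 of 245 members, 52 had an unadjusted p under 0.05 and DESeq2 called 15. Adjusted over the list alone these lists gave 7 of 7 macrophage, 5 of 7 podocyte, 3 of 8 endothelial, 3 of 6 B cell, 2 of 2 urothelium, 2 of 6 tubule injury, 1 of 6 dendritic cell and 1 of 6 NK cell genes, and 0 in the remaining lists. With the block, 6 distal transport, 3 macrophage genes and 1 dendritic cell gene passed. For 6858 genes of at least 20 CPM the median range of group means was 0.22, and the median SD between wells within groups was 0.10. A range over 8 means is wider than such an SD even without a difference between groups. These values therefore do not show that the groups differed by more than the wells for most genes.

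Mitochondrial transcripts took a larger share of UMIs in doublets, 11.1% ± 0.334 of their sums against 8.40% ± 0.172 in singlets. Cells of either well reached at most 59.99%, so droplets with a higher share are not covered. The median per droplet was 9.38% ± 0.286 in doublets, 4.29% ± 0.261 in singlets and 6.93% ± 0.295 in simulated pairs. Endothelial-like cells went from 3.76% of UMIs in singlets to 11.1% in doublets, NK cell-like cells from 6.48% to 12.8%, T cell-like cells from 4.47% to 9.88%, neutrophil-like cells from 3.85% to 9.28%, B cell-like cells from 4.22% to 9.47% and macrophage-like cells from 2.93% to 8.01%. Smaller differences were found in stromal and smooth muscle-like cells (4.46% and 7.55%), dendritic-like cells (1.38% and 4.41%) and thin limb-like cells (4.00% and 6.14%). Thick ascending limb-like cells had 23.7% and 23.8%, proximal tubule-like cells 19.0% and 20.3%, and principal-like cells 7.69% and 8.95%. The UMIs of a doublet include those of its partner, whatever class the droplet was given, and simulated pairs were not compared by class. The values by class therefore do not show a change in the cells of a class.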

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

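The tests of carry-over in balanced doublets, of red blood cells that left haemoglobin UMIs as the whole cause, of partners with little RNA of any type and of added UMIs, and the exclusion of the haemoglobin-rich cluster, were chosen after the result was seen. The design gives no biological groups, so no biological explanation was tested for any pattern.

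The authors' cell type names in well 2, which no comparison uses, were compared with marker content in CMO singlets, by a rule set after the values had been seen. For 3 of 15 names the markers of the class the name stands for held a smaller share of UMIs than in all 11312 singlets of the well, and for the other 12 they held 2.89 to 78.6 times that share. Singlets named A-IC (290) held intercalated cell markers at 0.0263 times and proximal tubule markers at 12.1 times the share in all singlets, and 98.3% of them fell in the proximal tubule-like class. Erythroid markers stood at 20 times that share in their summed counts, the largest fold for this name. Singlets named Fib (153) held stromal and smooth muscle markers at 0.372 times and macrophage markers at 2.96 times that share, and 66.7% fell in the macrophage-like class. The 5 singlets named B-IC held 0 intercalated cell marker UMIs, with T cell markers at 27.5 times the share in all singlets.

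Doublets held 1.55 times the UMIs of singlets, for which small amounts of CMO carried over onto droplets with 1 cell stay open. The 2-group doublets with the most balanced CMO counts had a ratio of 1.37 ± 0.036. Those with the least balanced counts had 1.49 in well 1 and 1.54 in well 2. Balance does not isolate carry-over, because CMO labelling differed between classes. Median CMO counts of singlets ran from 150.5 in T cell-like to 1228 in principal-like cells. UMIs that do not add up stay open: 2-group doublets positive for a rare class pair held 0.924 ± 0.074 times the UMIs of simulated pairs positive for the same pair, and the spread reaches below the 90% set as the bound against them. Versions over all doublets were set aside, 1.007 ± 0.033 because 38.7% of the positive doublets carried 3 or more groups, and 0.745 ± 0.0016 over any class pair because 79.3% of singlets and 98.7% of simulated pairs were positive by it. Partners that carry little RNA may account for part of the gap. In 2-group doublets rare class pairs reached only 32.3% ± 4.0 of the rise that simulated pairs gave (40.0% in all doublets). CMO-bearing fragments beside 1 cell, or CMO carried over onto a droplet with 1 cell, would give this too. Red blood cells that left haemoglobin UMIs are argued against as the whole cause by the test added later: without droplets with such a UMI −3.43% ± 1.3 of the gap to simulated pairs closed. The test fixed beforehand, of partners with little RNA such as red blood cells, could not decide. Its ratio, without droplets with a haemoglobin UMI, was 1.52 ± 0.0041 and lay between the bounds for and against. Red blood cells that left no haemoglobin UMI stay open.

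Haemoglobin was higher in doublets, for which free haemoglobin RNA spread over all droplets is argued against, since doublets with at least 20 haemoglobin UMIs held 98.6% ± 0.264 of the doublets' haemoglobin UMIs. Red blood cells as partners may be the source: such 2-group doublets held 0.715 ± 0.063 times the other UMIs of singlets, and 0.365% and 0.325% of doublets were so, against 0.0635% and 0.0707% of singlets. The rise rests on 33 and 25 doublets, and its calls ended at 500 genes per cell. Without the unnamed cluster of high haemoglobin and mitochondrial content Hbb-bs went from log2 1.44 (SE 0.059) to 2.38 (SE 0.476), and Hba-a1 from 1.29 (SE 0.053) to 2.16 (SE 0.494), and the calls ended because the spread between wells grew (adjusted p = 0.0543 and 0.0894, edgeR). Over the alternatives the adjusted p ranged from 2.51e-106 to 0.0543 for Hbb-bs and from 6.38e-92 to 0.0894 for Hba-a1.

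Cell classes were unequal in doublets and singlets, in large part as in simulated pairs, and the correlations given here use the ratio to singlets. A difference in CMO labelling between classes stays open, with a Spearman correlation across 14 classes of 0.292 (two-sided permutation p = 0.308) and Pearson's r with the log2 count of 0.374 (permutation p = 0.191). Without the 2 classes farthest from the median they were −0.03 and 0.024. A difference in RNA content also stays open, at 0.385 (permutation p = 0.173) and 0.422 (permutation p = 0.137), and 0.601 and 0.554 without the 2 farthest classes. Both permutation p-values of the rank correlations were 0.308 after adjustment over both relations.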

How the results depend on the processing

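The exclusions of the haemoglobin-rich cluster and of cells with a haemoglobin UMI, and the restriction to rare-pair doublets, were chosen after the result was seen; the other alternatives were not. The cause was not tested for any change given here unless stated. Of comparisons of main results, 44 stayed within their limits and 30 moved. The limit was a fixed fold for counts and the SD over the wells for other values. A single well always lies within that SD of the mean of both. Leaving out a well therefore could not move the doublet share, UMI ratio, AUROC or marker share, and those comparisons among the 44 carry no information. Of comparisons of single genes and classes, 343 stayed, 47 were no longer past the threshold, 57 moved and 1 reversed, the neutrophil-like share by highest marker score (−0.082).

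The 214 genes of the doublet test became 1684 with the well as a block, 64 with the authors' calls in well 2, 107 after thinning (75 of the 214, 1 with the opposite sign; 335 with the block) and 136 without haemoglobin UMIs (937 with the block), and ranged from 159 to 447 on leaving out a sum. The lone sum of a class is then assumed to vary like the others. With the authors' calls and the block together 0 genes passed in edgeR (1501 at an unadjusted p under 0.05), with callers mixed between wells. Of the 20 named genes 8 passed with the authors' calls, 14 at posterior 0.9, 15 at 500 genes, 15 after thinning, 15 without the haemoglobin-rich cluster and 18 to 20 on leaving out a sum. Of the 16 that could be tested without haemoglobin UMIs 10 passed. The block changed no camera call. The 37 genes of the group test became 71 with the block, 100 at posterior 0.9, 170 with DESeq2, 32 by the background rule and 45 with the authors' calls in well 2. Of the 37 genes themselves, 35 passed at posterior 0.9, 31 with DESeq2, 28 by the background rule and 25 with the authors' calls. The 5 classes past 0.3, counted by the mean of the wells with the same sign in both, became 8 at posterior 0.9, 6 with the authors' calls (principal-like lost, at 0.249), 6 by highest marker score (neutrophil-like lost), 4 at 500 genes and 4 at a mitochondrial share of at most 30% (neutrophil-like lost at both, at 0.248 and 0.221), and 6 in each well alone.

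Values with the authors' calls are means of their calls in well 2 and the mixture in well 1. The doublet share was 35.7% at posterior 0.9, 39.8% by the background rule, 39.6% with the authors' calls (37.5% in well 2) and 42.9% at 500 genes, and 40.4% to 41.8% in single wells. The UMI ratio was 1.496 by means, 1.47 with the authors' calls (1.41 in well 2), 1.43 at 500 genes and 1.49 at a mitochondrial share of at most 30%, and 1.54 to 1.56 in single wells. The Scrublet AUROC was 0.674 at posterior 0.9, 0.661 with the authors' calls, 0.648 within depth bins, 0.678 for doublets with markers of 2 classes and 0.949 for rare pairs, and 0.664 to 0.669 in single wells. Doublets with markers of 2 classes were 95.3% at 2 UMIs, 77.5% at 5, 90.3% at posterior 0.9, 89.6% by the background rule, 87.6% with the authors' calls, 93.6% at 500 genes, 94.8% at a mitochondrial share of at most 30% and 47.3% after thinning, since fewer UMIs leave fewer markers, and 89.4% to 89.5% in single wells.

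Not run were CMO calls from 2 of 3 CMOs, since the matrices hold sums per group, and leaving out a well in the group test, which leaves no residual degrees of freedom. Thinning lowers the depth of the sums but also weights droplets equally, so the part of depth in the fewer genes was not tested apart.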

Other observations

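The rare class pairs were chosen after the result was seen; the part gives values and no test. CMO labelling differed between cell classes. Principal-like and intercalated-like singlets had median CMO counts of 1228 and 1225, macrophage-like 860, dendritic-like 570 and endothelial-like 414. NK cell-like singlets had 178, T cell-like 150.5, B cell-like 192 and thick ascending limb-like 206. The share of a class that was negative for all CMO groups was 33.1% for NK cell-like, 26.9% for T cell-like, 25.4% for proximal tubule-like and 25.04% for thick ascending limb-like cells, against 0.577% for principal-like and 0.0123% for macrophage-like cells.

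The authors' computational call in well 2 marked 69.4% of NK cell-like, 61.3% of T cell-like and 60.4% of thin limb-like doublets, and 43.2% of thick ascending limb-like and 43.5% of distal convoluted tubule-like doublets. Among CMO singlets it marked 40.4% of NK cell-like and 8.30% of macrophage-like cells. It marked 96.5% of doublets and 73.0% of singlets positive for a rare class pair.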
